A study of Homo sapiens with 6 samples.

How the data were processed

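RNA-seq values were used from 6 frozen EHE tumours that, per the labels' protocols, came from surgical resection or autopsy; the labels do not say which tumour came from which. Total RNA was extracted with a commercial kit, polyadenylated RNA was taken, and libraries followed the DNBSeq protocol, per the labels' protocols. The submitters' processing notes name HISAT2 2.1.0, Cufflinks 2.2.1.3 and the genome build hg38, without roles or order. The counting program, the gene annotation, the multi-mapping rule and whether strand was used are not given in the sources used here. Genes that overlap or have near-identical copies may therefore share reads.

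Whole-number counts per gene for the 6 tumours were deposited by the authors in a table of the series with 60624 gene rows, not normalized. FPKM values (fragments per kilobase of transcript, scaled to the library total) were deposited by the authors in a table per tumour, with gene symbols. The FPKM files held 218 repeated rows of 108 gene identifiers, which were summed, and 22 counted genes without an FPKM row were set to 0. Each column of counts correlated best with the FPKM table of its own tumour (Spearman's rho 0.850 to 0.862, against at most 0.814 for another tumour). In each tumour 78 to 106 genes were listed at 0 FPKM although they had at least 1000 counts; the cause is not known here, and these zeros stayed as deposited in the main results.

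Symbols came from the FPKM tables. Positions and biotypes came from GENCODE 29 on GRCh38, which matched 58437 of the 60624 identifiers. FPKM corrects for transcript length and was the unit for levels, on the scale log2(FPKM + 1), where differences of low genes are understated. Counts were the unit for variability, similarity and correlations: edgeR 4.0.16 (R 4.3.3) kept 14194 genes with its default filter at a minimum count of 10, which with 1 group demands every sample, computed TMM factors and gave log2 CPM with a prior count of 2. The dispersion was fitted by edgeR without groups, and DESeq2 1.42.0 gave alternative size factors and dispersions. No differential test was possible with 1 group. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

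Before the data were examined, 39 gene lists with 469 genes, 8 comparisons within tumours, 10 correlations, the tests, the alternatives and the rule for naming genes were fixed. A list's level in a tumour was the median over its members, set against 10000 random lists of the same size drawn from detected protein-coding genes; the percentile describes these libraries and is not a p-value. Comparisons within tumours used an exact two-sided sign-flip permutation test over 64 patterns, with Benjamini-Hochberg adjustment over the 8. Adjusted p-values of at most 0.05 were counted as passing, a limit set after the files had been seen. Correlations used list scores (the mean over filtered members of log2 CPM centred per gene) and exact permutation of the 720 pairings, adjusted over the 10. Variability of a list was its median SD of log2 CPM, as a percentile among 10000 random lists matched on expression in 20 bins. Poisson variation was tested per gene by chi-square.

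The genes named were all fusion partners and paralogs; up to 4 per other list (the 2 with the highest mean level, the 1 with the largest SD and the 1 with the lowest level); the 15 with the highest mean level; the 20 most variable protein-coding genes with a mean log2 CPM of at least 3; and the 10 steadiest with a mean of at least 5. Because the tumours are human, genes that report sex, immune receptor segments, HLA genes and genes with common germline deletions were never named or ranked. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

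The Poisson test was run on simulated counts for the same 14194 genes. It recovered 92% of 50 genes changed 1.5-fold in 1 tumour and 100% of 50 changed 2-fold. It also called 1.91% of unchanged genes, and these outnumbered the changed genes called. Most calls in this simulation were therefore false, so it does not show that the test holds its error rate. A simulated coefficient of variation of 0.8 was returned as 0.797. A simulated list with doubled SD reached percentile 100, and 1 of 31 other lists fell outside the central 95%. The sign-flip test called 2.8% of simulated null comparisons. Its smallest exact p of 0.03125 sets that rate by construction, so the share says nothing about the real comparisons.

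Alternatives were another pseudocount (0.1), means over members, CPM without length, filtered members, random lists from filtered genes, median-of-ratios or library size scaling, no filter, a prior count of 0.5, FPKM or medians for correlations, the 500 most variable genes for similarity, and leaving out each tumour. Leaving out FPKM zeros of genes with at least 10 counts, CPM per kilobase of exon, leaving out the genes shared by the hypoxia and tip cell lists, leaving out each tumour for correlations, similarity and abundant genes, and the stroma test with KIT kept or over filtered members were added after seeing the data. In the closing sections, 10 genes of interstitial cells of Cajal and 19 of hepatocytes were listed as markers absent from the fixed lists before their values were seen.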

Results

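Polyadenylated RNA was sequenced from 6 frozen specimens labelled as epithelioid hemangioendothelioma (EHE). EHE is a rare vascular sarcoma in which WWTR1 is usually fused to CAMTA1 and YAP1, less often, to TFE3. The specimens form a single group, tumours 1 to 6 as numbered in the labels, without normal tissue or another tumour type, so no test between groups existed. The labels do not state that each tumour came from a separate donor, and the p-values measure only the spread between these samples. The counts summed to 34208647 in tumour 2, the lowest total, and to 39062786 in tumour 1, the highest. Before TMM scaling, a single count was worth 0.0256 to 0.0292 CPM (counts scaled to a common library total). A count of 0 then allowed a level of up to 0.0768 to 0.0877 CPM (3 counts, covering counting error only). The CPM values printed for genes are TMM-scaled, and on that scale 3 counts came to 0.0725 CPM in tumour 4 and 0.0879 CPM in tumour 2. Values below are means ± SD over the 6 tumours unless a tumour is named. They include tumour 4, whose whole profile stood apart from those of the others. For that library, tissue of another lineage behind the label stays open, as weighed in the closing sections. The means and SDs therefore describe the libraries as labelled and may not describe EHE alone.

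The partner genes of the EHE fusions were transcribed in 6 of 6 tumours. CAMTA1, which encodes a calmodulin-binding transcription activator, averaged 69.1 ± 25.6 FPKM, and WWTR1, which encodes the transcriptional coactivator TAZ, averaged 50.5 ± 37.8 FPKM. TFE3, a helix-loop-helix factor of the MiT family, stood at 29.5 ± 5.74 FPKM, and YAP1, the paralog of WWTR1, at 23.9 ± 10.8 FPKM. CAMTA1 exceeded its paralog CAMTA2 (28.8 ± 12.4 FPKM) and TFE3 exceeded TFEB (12.6 ± 4.89 FPKM), whereas WWTR1 and YAP1 changed order between tumours. MITF (4.56 ± 6.05 FPKM) and TFEC (0.71 ± 0.75 FPKM) were lower, with MITF at 80.4 CPM in tumour 4 and 6.07 to 17.5 CPM in the others.

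WWTR1 (ENSG00000018408) lies on chromosome 3 at 149517235 to 149736714, and CAMTA1 (ENSG00000171735) on chromosome 1 at 6785324 to 7769706. YAP1 (ENSG00000137693) lies on chromosome 11 at 102110461 to 102233423, and TFE3 (ENSG00000068323) on chromosome X at 49028726 to 49043486. These GRCh38 positions span each whole gene, exons and introns, and the values were summed over the gene, so neither a fusion transcript nor an exon was measured separately.

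Whether 1 paralog dominated was compared within each tumour on the log2(FPKM + 1) scale. CAMTA1 exceeded CAMTA2 by 1.26 ± 0.92 in 6 of 6 tumours (exact two-sided sign-flip permutation p = 0.03125, adjusted p = 0.05 over 8 comparisons). TFE3 exceeded TFEB by 1.21 ± 0.51 in 6 of 6 tumours (exact sign-flip p = 0.03125, adjusted p = 0.05). WWTR1 minus YAP1 was 0.78 ± 1.47, positive in 4 of 6 tumours, and did not pass (exact sign-flip p = 0.219, adjusted p = 0.219). Across the 8 comparisons 5 reached 0.03125, the smallest p that 6 tumours allow, and all 5 therefore stood exactly at the limit of 0.05, which was set after the files had been seen; with 4 at that minimum the adjusted p would be 0.0625. None of the 5 passed in CPM without length correction (adjusted p from 0.0625 to 0.0833, exact sign-flip tests) or in CPM per kilobase of exon (0.0833 to 0.15). In CPM, CAMTA1 lay below CAMTA2 in tumour 4 (67.7 against 92.0 CPM), and that comparison no longer passed (exact sign-flip p = 0.0625, adjusted p = 0.0833).

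**Figure D1:**
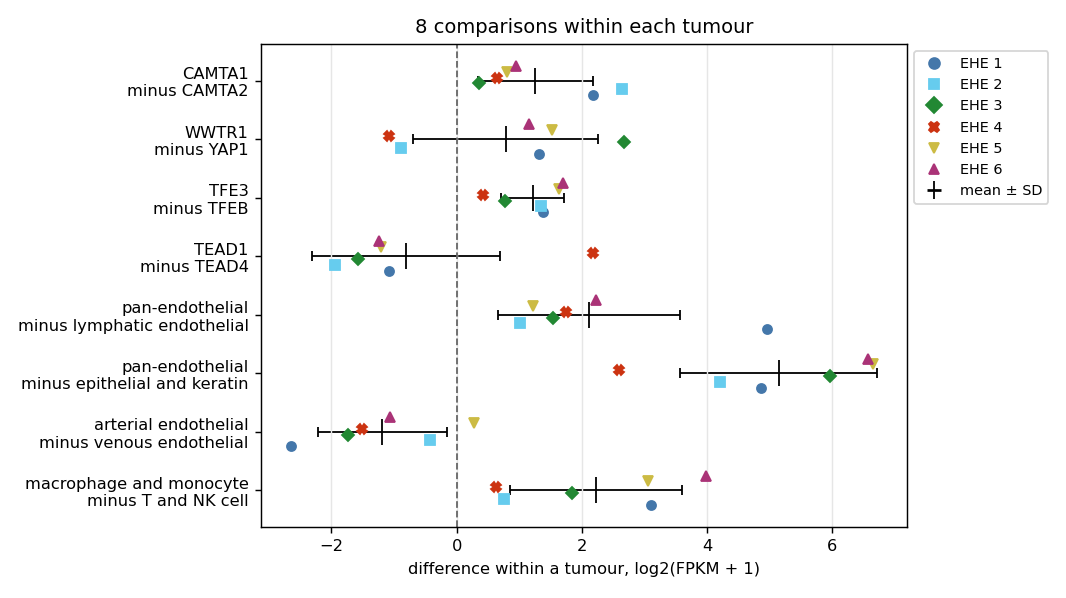
Differences within each of the 6 tumours for the 8 comparisons fixed before the data were examined, as log2(FPKM + 1) on the horizontal axis; symbols are tumours and black bars the mean ± SD. CAMTA1 minus CAMTA2 was positive in 6 of 6 tumours, and TEAD1 minus TEAD4 was positive only in tumour 4.

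**Figure D2:**
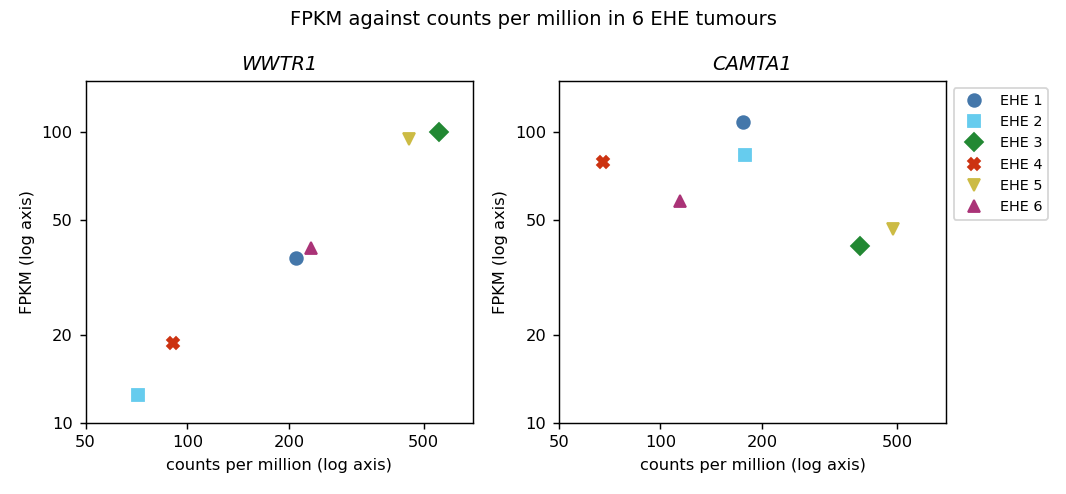
FPKM (vertical) against CPM (horizontal), both on log axes, for WWTR1 and CAMTA1 in the 6 tumours. WWTR1 ranked the 6 tumours in the same order in both units, whereas CAMTA1 was highest in CPM in tumours 5 and 3 (488 and 389 CPM) and lowest in FPKM there (46.3 and 40.4 FPKM).

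Genes bound by YAP and TAZ through TEAD factors were at high levels in 5 of 6 tumours. The median of the 22 YAP/TAZ target genes was 4.29 ± 0.88 log2(FPKM + 1), at or above the 95th percentile of random gene lists in 5 tumours and at percentile 72.5 in tumour 4. CCN1 and CCN2, which encode secreted matricellular proteins, averaged 433 ± 329 and 217 ± 135 FPKM. ANKRD1, a nuclear ankyrin-repeat protein, stood at 176, 173 and 121 CPM in tumours 2, 5 and 6 and at 0.459 to 2.09 CPM in the others, and FOXF2 averaged 1.09 ± 1.02 FPKM. Tumour 5 held the highest value for 10 of the 22 genes and tumour 4 the lowest for 14, or for 13 with scaling by library size alone.

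Among TEAD factors and VGLL cofactors (3.16 ± 0.85, percentiles 24.6 to 90.0), TEAD2 (39.1 ± 30.4 FPKM), VGLL4 (37.5 ± 5.65 FPKM) and TEAD4 (34.2 ± 20.8 FPKM) had the highest means and VGLL2 (0.02 ± 0.03 FPKM) the lowest. The rank of TEAD2 rested on tumour 4, where it reached 101 FPKM. In each other tumour TEAD2 (22.4 to 31.1 FPKM) lay below both VGLL4 (32.2 to 45.2 FPKM) and TEAD4 (26.0 to 60.6 FPKM). TEAD4 ranged from 48.5 to 117 CPM in 5 tumours and stood at 0.386 CPM, 16 counts, in tumour 4, where TEAD2 reached 167 CPM against 45.7 to 58.7 CPM elsewhere. TEAD1 minus TEAD4 averaged −0.81 (range −1.94 to 2.18), positive in 1 of 6 tumours, and did not pass (exact sign-flip p = 0.219, adjusted p = 0.219). That difference was −1.41 without tumour 4. In CPM without length correction it was 1.78, positive in 6 of 6 tumours (exact sign-flip p = 0.03125, adjusted p = 0.0625). That unit does not put genes of unlike length on a common scale, and in CPM per kilobase of exon the sign did not change.

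The kinases and adaptors of the Hippo pathway, which restrains YAP and TAZ, had a median of 2.97 ± 0.42 (percentiles 60.6 to 93.9). MOB1A (31.1 ± 5.20 FPKM) and MAP4K4 (29.7 ± 9.86 FPKM) led this list, and AMOT was lowest (1.26 ± 1.01 FPKM). WWC1 stood at 72.1 CPM in tumour 4 and 6.85 to 32.8 CPM in the others. Subunits of the ATAC and SAGA histone acetyltransferase complexes stood at 3.08 ± 0.38 (percentiles 68.9 to 92.4), led by TADA3 (45.9 ± 21.9 FPKM) and KAT2A (19.5 ± 18.1 FPKM). KAT2A was 53.9 FPKM in tumour 4 and was listed at 0 FPKM in tumour 5 despite 695 counts, against 13.1 to 18.1 FPKM in the others. KAT2B stood at 345 CPM in tumour 4 and 16.4 to 44.4 CPM elsewhere, and KAT14 averaged 3.05 ± 0.68 FPKM. The mean percentile of the Hippo list went from 74.9 to 93.8 in CPM without length and to 40.8 against random lists from filtered genes, and that of the ATAC and SAGA list from 77.4 to 93.6 and 47.2.

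Genes of the endothelium were high in 5 of the 6 tumours. The 20 pan-endothelial genes had a median of 5.79 ± 1.78 log2(FPKM + 1), at percentile 99.99 or 100 in 5 tumours and at 55.9 in tumour 4, which held the lowest value for 17 of the 20. ECSCR, an endothelial surface protein, averaged 504 ± 329 FPKM, and EGFL7, a secreted endothelial protein, 424 ± 292 FPKM, while the VEGF receptor FLT1 was the lowest member (6.56 FPKM on average, 12.3 to 107 CPM). In tumour 4 ECSCR stood at 0.749 CPM and EGFL7 at 28.2 CPM, against 41.0 to 145 and 469 to 1243 CPM in the others. The pan-endothelial median exceeded the lymphatic one by 2.12 ± 1.45 and the epithelial one by 5.14 ± 1.58, each in 6 of 6 tumours (exact sign-flip p = 0.03125 and adjusted p = 0.05 for both).

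Lymphatic endothelial genes (3.67 ± 1.70) reached the 95th percentile in 4 of 6 tumours. MMRN1 averaged 90.6 ± 62.2 FPKM and TFF3 291 ± 495 FPKM, with 682 CPM of TFF3 in tumour 3 and 2.37 CPM in tumour 4. RELN ranged from 0.485 CPM in tumour 3 to 679 CPM in tumour 5, and LYVE1, a hyaluronan receptor of lymphatic vessels, averaged 6.27 ± 4.82 FPKM. In CPM the pan-endothelial median did not pass against the lymphatic one (exact sign-flip p = 0.0625, adjusted p = 0.0833).

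Venous genes (4.29 ± 1.48) were at or above the 95th percentile in 3 tumours and arterial genes (3.10 ± 0.95) in 2. SELP, the adhesion molecule P-selectin, averaged 131 ± 146 FPKM, and NR2F2, a transcription factor of venous identity, 97.2 ± 64.9 FPKM, while SELE was low (0.91 ± 1.12 FPKM). GJA4, an arterial gap junction protein, averaged 256 ± 282 FPKM, FBLN5 43.7 ± 26.1 FPKM and SEMA3G 1.84 ± 1.76 FPKM. Arterial minus venous was −1.19 ± 1.03, positive in 1 of 6 tumours, and did not pass (exact sign-flip p = 0.0625, adjusted p = 0.0833). It passed when each list was summarised by its mean (−0.942, adjusted p = 0.05, exact sign-flip test) or by members passing the count filter (−1.73, adjusted p = 0.0417, exact sign-flip test).

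Capillary genes were lower (1.67 ± 0.50, percentiles 14.9 to 47.9), at a mean percentile that went from 30.4 to 6.59 against random lists from filtered genes and to 71.4 with filtered members, with RGCC at 63.9 ± 39.3, EDNRB at 58.1 ± 58.3, FCN3 at 4.05 ± 5.89 and CA4 at 0.30 ± 0.52 FPKM. FCN3 was 15.7 FPKM in tumour 2 and at most 3.82 FPKM elsewhere, and CA4 1.29 FPKM in tumour 4 and at most 0.457 FPKM elsewhere. Genes of tip cells and angiogenesis (3.65 ± 1.18) reached the 95th percentile in 4 tumours. ADM, which encodes the vasoactive peptide adrenomedullin, ranged from 21.7 CPM in tumour 4 to 1868 CPM in tumour 3. ANGPT2, a ligand of the TEK receptor, ranged from 5.12 CPM in tumour 4 to 1730 CPM in tumour 3, and the basement membrane collagen COL4A2 from 84.0 CPM in tumour 4 to 2535 CPM in tumour 6.

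**Figure D3:**
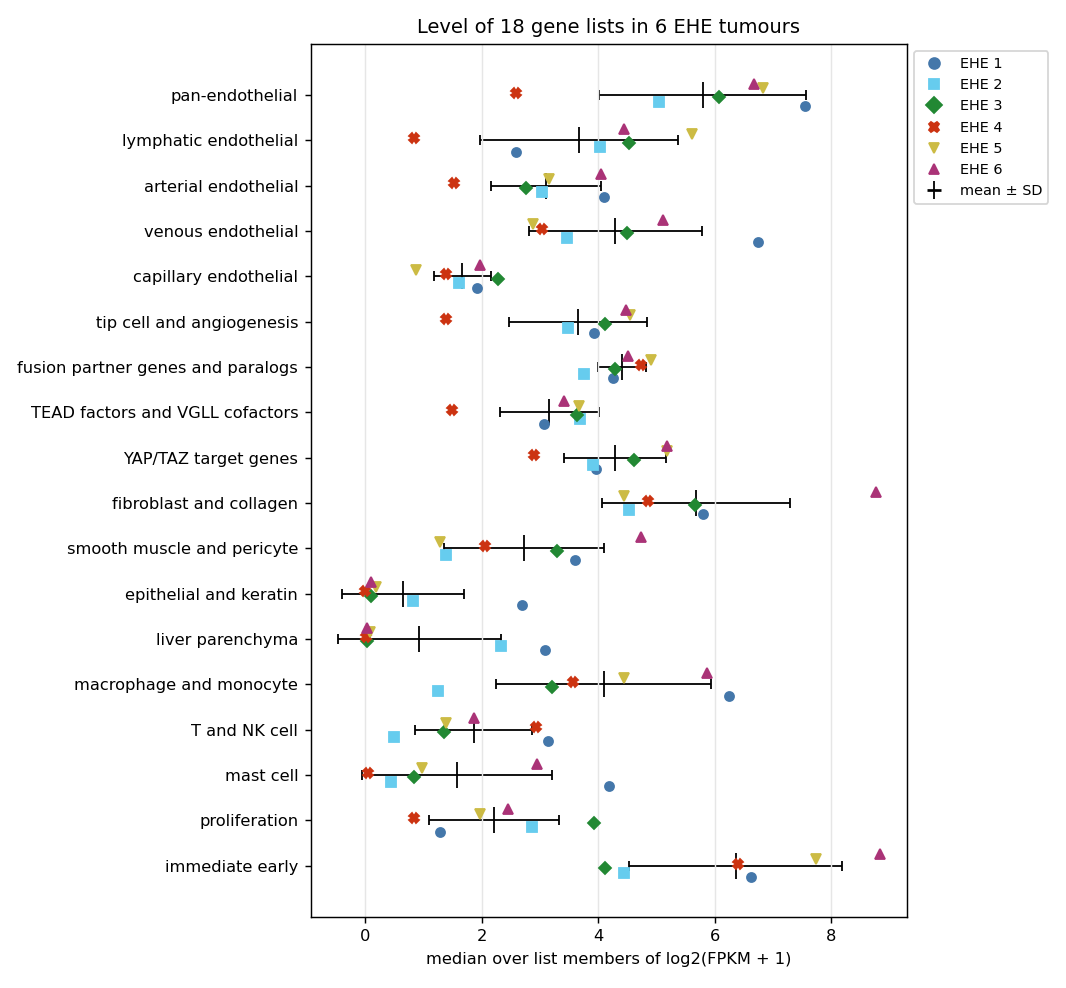
Median log2(FPKM + 1) over the members of 18 of the 39 gene lists in each of the 6 tumours; symbols are tumours and black bars the mean ± SD. The pan-endothelial median lay between 5.04 and 7.54 in 5 tumours and at 2.59 in tumour 4, and the fibroblast and collagen median reached 8.77 in tumour 6.

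Genes of fibroblasts and collagen were high in 6 of 6 tumours (5.67 ± 1.62, percentiles 99.3 to 100). COL1A1, the main fibrillar collagen, averaged 882 ± 1688 FPKM, with 33649 CPM in tumour 6 and 312 to 3804 CPM in the others, and FN1, fibronectin, averaged 845 ± 674 FPKM. Tumour 6 held the highest value for 12 of the 14 genes, among them SFRP2 (1140 CPM, against 0.205 to 87.7 CPM elsewhere), while PDGFRA averaged 5.54 ± 5.85 FPKM. Of the proteoglycan and cartilage-type genes (1.37 ± 1.04, mean percentile 25.3, or 89.7 with filtered members), BGN averaged 1146 ± 1337 and VCAN 121 ± 99.5 FPKM, and COL11A1 stood at 194 CPM in tumour 6 and at up to 15.05 CPM elsewhere. BGN was 3657 FPKM in tumour 6 and 10.9 to 1424 FPKM in the others. Smooth muscle and pericyte genes (2.72 ± 1.38) were led by TAGLN (447 ± 339 FPKM) and ACTA2 (269 ± 266 FPKM), with DES at 8.15 ± 9.41 FPKM.

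Macrophage genes (4.09 ± 1.85) exceeded T and NK cell genes (1.86 ± 1.01) by 2.23 ± 1.37 in 6 of 6 tumours (exact sign-flip p = 0.03125, adjusted p = 0.05). The complement genes C1QA (118 ± 93.6 FPKM), C1QB (119 ± 97.4 FPKM) and C1QC (104 ± 87.8 FPKM), typical of tissue macrophages, led the former list. Tumour 2 had the lowest value for 12 of 12 macrophage genes with at least 10 counts, with C1QB at 1.47 CPM against 44.9 to 285 CPM in the others. Of the T and NK cell genes, GNLY averaged 21.4 ± 23.2, NKG7 11.4 ± 7.99 and CD3G 0.44 ± 0.48 FPKM. With the mean over members, the comparison did not pass (1.80, exact sign-flip p = 0.0625, adjusted p = 0.0833).

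Neutrophil genes stood at 2.59 ± 1.08 and mast cell genes at 1.57 ± 1.63, and B and plasma cell genes (0.37 ± 0.27) were low. Erythroid genes had a low median (0.24 ± 0.14, mean percentile 2.61), but HBB, chosen after its values were seen, averaged 107 ± 46.1 FPKM, and the mean percentile was 54.1 with means over members and 99.3 with the members past the filter. S100A9 was 0.386 CPM in tumour 4 and 11.6 to 56.0 CPM in the others, and JCHAIN was highest in tumour 4 (40.4 CPM) and tumour 1 (26.2 CPM). KIT, a receptor tyrosine kinase, stood at 7795 CPM in tumour 4 and 12.8 to 48.6 CPM in the others. CPA3, a mast cell protease, was 77.7 CPM in tumour 1 and had 0 counts in tumour 4, which allows up to 0.0822 CPM before TMM scaling. GATA2, a transcription factor of mast cells and endothelium, was 1.26 CPM in tumour 4 and 124 to 396 CPM in the others.

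Epithelial genes as a list (0.65 ± 1.04) were low in 5 tumours (percentiles 0.03 to 9.36) but stood at 2.69 in tumour 1 (percentile 60.8), and KRT18, a keratin of simple epithelia, averaged 803 ± 539 FPKM. KRT18 ranged from 328 to 1574 CPM in 5 tumours and stood at 3.43 CPM in tumour 4, and KRT7 reached 86.6 CPM in tumour 1. CLDN7 was listed at 0 FPKM in 6 of 6 tumours although it had up to 8.06 CPM, and KRT8, chosen after its values were seen, was listed at 0 FPKM in tumours 2, 3, 5 and 6 with 1733 to 3779 counts. Keratinocyte (0.13 ± 0.18), lung epithelial (0.02 ± 0.03) and skeletal muscle genes (0.05 ± 0.07) stood at or below the 5th percentile in 6 of 6 tumours, and mesothelial (0.32 ± 0.30), adipocyte (0.22 ± 0.27) and neuronal genes (0.42 ± 0.17) in 5 of 6. With filtered members the mean percentile rose from 1.90 to 28.9 for adipocyte genes, from 3.14 to 65.8 for neuronal genes and from 6.24 to 68.1 for osteoblast and osteoclast genes. Osteoblast and osteoclast genes (0.44 ± 0.68) reached 1.79 in tumour 6, where IBSP, bone sialoprotein, stood at 28.1 CPM against up to 4.48 CPM elsewhere. Liver genes (0.93 ± 1.40) had medians of 3.08 in tumour 1 and 2.33 in tumour 2 and of 0.02 to 0.07 in the others, with ALB, serum albumin, at 78.6, 82.1 and 0.145 to 0.350 CPM.

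The proliferation list (2.22 ± 1.12) ranged from percentile 5.38 in tumour 4 to 97.6 in tumour 3, which had the highest value for 12 of 18 genes. UBE2C, a ubiquitin-conjugating enzyme of mitosis, ranged from 0.193 CPM in tumour 4 to 41.6 CPM in tumour 3, and PCNA, the replication clamp, averaged 42.7 ± 14.8 FPKM. Cell cycle inhibitors and G1 regulators were higher (4.52 ± 0.57), led by CCND1 (190 ± 93.2 FPKM) and the p53 target CDKN1A (175 ± 146 FPKM), with CDK6 at 24.9 to 74.9 CPM. The variability of proliferation genes lay at percentile 98.4 of matched random lists, but at 96.6 without tumour 1 and 93.5 without tumour 3, and that of inhibitors and G1 regulators at 91.0. Hypoxia genes (5.15 ± 1.43) reached the 95th percentile in 5 tumours, with the glycolytic enzyme ENO1 at 555 ± 345 FPKM and ANGPTL4 at 1.59 CPM in tumour 4 and 55.3 to 305 CPM in the others.

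Immediate early genes (6.36 ± 1.83) and heat shock genes (6.56 ± 0.53) were at or above the 95th percentile in 6 of 6 tumours. FOSB, an AP-1 subunit, ranged from 2.08 and 2.94 CPM in tumours 2 and 3 to 1688 CPM in tumour 6; the labels do not say which tumours came from resection and which from autopsy. FOS averaged 373 ± 538 FPKM, with 1438 FPKM in tumour 6 and 8.07 to 324 FPKM in the others, and DUSP1 averaged 465 ± 236 FPKM. HSPB1 averaged 2107 ± 719 and HSP90AA1 315 ± 106 FPKM. Interferon response genes stood at 3.35 ± 0.49, with IFI6 at 87.2 ± 58.0 FPKM. Melanosome and lysosome genes of the MiT family (4.54 ± 0.48) were led by the proteases CTSD (440 ± 157 FPKM) and CTSB (342 ± 64.7 FPKM), with GPNMB at 19.8 ± 21.2 FPKM.

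Mitochondrially encoded genes took 3.53 to 10.96% of the counts, and MT-CO1, a subunit of cytochrome c oxidase, ranged from 1340 CPM in tumour 3 to 25429 CPM in tumour 1. MT-ND6 had the same extremes (135 and 1776 CPM). MT-CO2 and MT-ND3 were instead highest in tumour 2 (10486 and 3489 CPM), with 6744 and 3197 CPM in tumour 3, so these genes did not vary together. Cytosolic ribosomal protein genes (10.45 ± 0.67) were led by RPL13 (2401 ± 907 FPKM) and RPS3 (2367 ± 966 FPKM), and 15 of the 16 were lowest in tumour 4 under each of 3 scalings. Housekeeping genes (6.86 ± 0.46) were led by B2M (5941 ± 620 FPKM) and ACTB (4911 ± 928 FPKM), while TFRC, the transferrin receptor, ranged from 11.5 to 290 CPM. In all, 6 of the 39 lists were at or above the 95th percentile in every tumour, and 11 without tumour 4; 3 were at or below the 5th percentile in every tumour, and 5 without tumour 4.

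**Figure D4:**
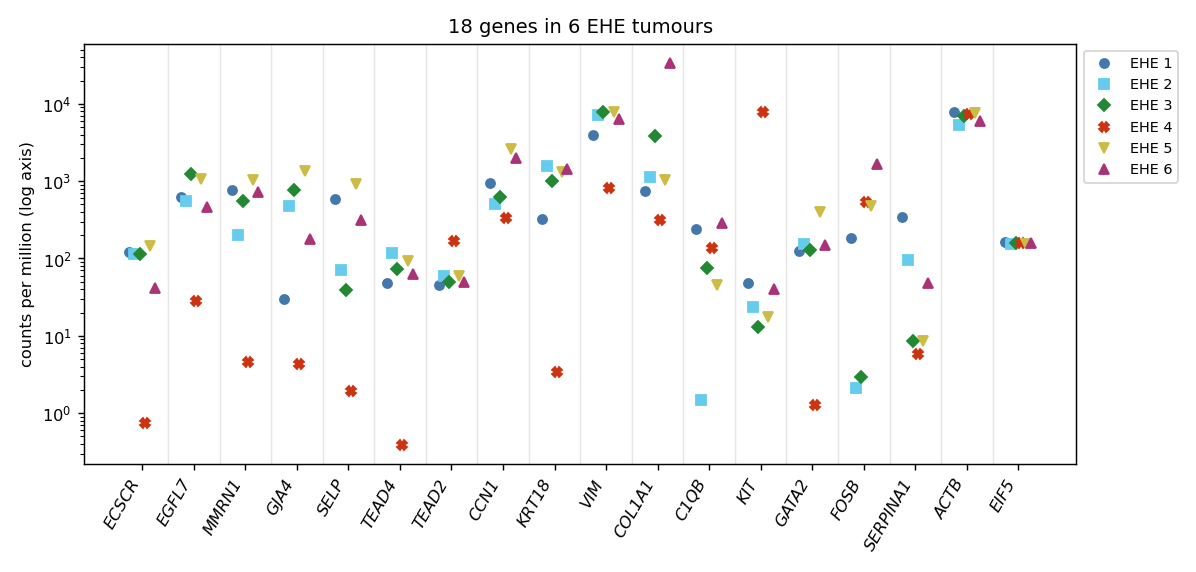
CPM on a log axis of 18 genes in each of the 6 tumours; symbols are tumours. In tumour 4 the endothelial genes ECSCR and EGFL7, TEAD4 and KRT18 were lowest and KIT highest (7795 CPM), whereas ACTB (5272 to 7908 CPM) and EIF5 (152 to 163 CPM) were similar in the 6 tumours.

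Tumour 4 stood apart from the others in its whole profile. It had 432 genes at least 4 times higher and 579 genes at least 4 times lower than in every other tumour, whereas the other tumours had 30 to 136 and 2 to 31 such genes. UNC5D, SHISA6 and EDN3, chosen after their values were seen as the 3 with the widest margin, stood at 284, 251 and 982 CPM in tumour 4, while EDN3, the highest of them elsewhere, stood at up to 2.95 CPM. Spearman's rho across 14194 genes was 0.695 to 0.751 between tumour 4 and the others and 0.844 to 0.929 among the other 5, with a median of 0.860 over all pairs; genes are not independent replicates. The first principal component held 48.6% of the variance and placed tumour 4 at 167, against −51.6 to −0.628 for the others. Scaling by library size alone moved the median of all genes in tumour 4 by 0.22 on the log2 scale relative to TMM scaling. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 335 to 1370).

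The common biological coefficient of variation from edgeR was 0.638, or 0.555 without tumour 4. Of 14194 genes, 14113 varied beyond Poisson error (chi-square test, adjusted at 0.05), which at this depth says little about the size of the differences. In simulation the test called 1.91% of unchanged genes, so this number may include false calls. Of 32 lists with at least 3 members past the filter, 18 lay in the upper tail, outside the central 95% of expression-matched random lists, among them the lymphatic, pan-endothelial, venous, fibroblast, macrophage and smooth muscle lists (percentile 100 each). With each tumour left out in turn, 16 to 21 lists did; proliferation (93.5), interferon response (96.3) and epithelial genes (95.2) left the upper tail at their lowest. The YAP/TAZ targets lay at percentile 99.99, and Hippo kinases (44.4), housekeeping genes (42.0) and ATAC and SAGA subunits (35.3) in the middle. The ribosomal protein list lay at percentile 63.2, and at 0.42 without tumour 4.

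Among protein-coding genes with a mean of at least 3 log2 CPM, the most variable were NTS, the neuropeptide neurotensin, and RELN, with SDs of 4.82 and 4.66 log2 CPM. NTS stood at 910 CPM in tumour 3, 525 CPM in tumour 5 and 0.315 to 5.95 CPM in the others, and CPXM2 at 542 CPM in tumour 1 and 0.352 to 41.2 CPM elsewhere. Several reached their minimum in tumour 4, such as CRYAB, a small heat shock protein (2.71 CPM against 238 to 4187), and DSP, desmoplakin (0.145 against 18.3 to 411). PROM1 was highest there (836 CPM against 0.485 to 147). The steadiest genes in log2 CPM were EIF5, a translation initiation factor (158 ± 4.08 CPM), DEDD (40.8 ± 1.41 CPM) and SCAF4 (34.3 ± 1.38 CPM). By FPKM, EIF5 ranged from 25.5 to 83.2 and DEDD from 17.5 to 33.0, whereas SCAF4 ranged from 6.27 to 7.96.

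The list and gene scores in log2 CPM were correlated across the 6 tumours in 10 planned pairs, and none passed adjustment. Macrophage with T and NK cell genes came closest (Pearson's r = 0.916, exact permutation p = 0.00694, adjusted p = 0.0694, Spearman's rho = 0.943, exact permutation p = 0.0167), with r = 0.685 without the 2 tumours farthest from the median. Hypoxia with tip cell genes gave r = 0.888 (exact permutation p = 0.0222, adjusted p = 0.111, rho = 0.8286 with p = 0.0583), and 0.340 without the 2 farthest tumours. Leaving those out narrows the range, so this drop cannot show what the relation rested on. These lists share ADM and VEGFA, and without both genes r was 0.839 (exact permutation p = 0.0611, adjusted p = 0.194), or 0.198 without tumour 4 as well. Pan-endothelial with YAP/TAZ target genes gave r = 0.881 (exact permutation p = 0.0389, adjusted p = 0.130, rho = 0.714 with p = 0.136), 0.980 without the 2 farthest tumours and 0.511 without tumour 4. WWTR1 with CAMTA1 gave r = 0.757 (exact permutation p = 0.0778, adjusted p = 0.194, rho = 0.543 with p = 0.297), 0.932 without the 2 farthest tumours, and −0.762 when both were taken in FPKM.

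The other 6 relations had smaller coefficients (adjusted p from 0.267 to 0.497, exact permutation tests). YAP/TAZ targets gave r = 0.678 with fibroblast genes, 0.539 with CAMTA1, 0.544 with immediate early genes and 0.373 with smooth muscle genes (exact permutation p = 0.133, 0.278, 0.267 and 0.497; rho = 0.600, 0.2, 0.771 and 0.257 with p = 0.242, 0.714, 0.103 and 0.658). Without the 2 farthest tumours these became −0.67, −0.77, 0.922 and −0.29. Leaving out each tumour in turn, r ranged from 0.340 to 0.965 for fibroblast genes, 0.364 to 0.952 for immediate early genes (the highest without tumour 4) and 0.03 to 0.83 for smooth muscle genes. Pan-endothelial genes gave r = 0.640 with fibroblast genes and 0.432 with proliferation genes (exact permutation p = 0.204 and 0.429; rho = 0.543 and −0.0857 with p = 0.297 and 0.919). Without the 2 farthest tumours these became 0.248 and −0.92, and without tumour 4 they were 0.158 and −0.91.

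Apart from mitochondrial genes, the 15 highest in FPKM began with TMSB4XP6. After it came B2M, TMSB4X (5359 ± 978 FPKM), TMSB10 (5105 ± 2523 FPKM), the intermediate filament gene VIM (4972 ± 2364 FPKM), ACTB and EEF1A1 (4323 ± 1553 FPKM). TMSB4XP6, a pseudogene nearly identical to TMSB4X, was listed at 15095 ± 3366 FPKM and had 0 counts in 6 of 6 tumours, so its value is uncertain. TPT1, IFITM3, FTH1, RPS27, MT2A, GAPDH, CLU and IGFBP7 completed the 15, from 4314 ± 1881 to 2468 ± 1061 FPKM. VIM stood at 825 CPM in tumour 4 and 3993 to 7847 CPM in the others, and CLU, clusterin, at 60.8 CPM in tumour 4 and 1104 to 11264 CPM in the others. Ranked by CPM, 5 of these 15 remained among the top 15. The 10 most abundant genes took 5.96 to 11.98% of the counts of a tumour and the 100 most abundant 22.0 to 29.5%.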

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

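The tests of stroma and of depth and scaling were chosen only after the result was seen, whereas the test of marker genes absent from the fixed lists was written before their values were seen. Those markers were not held out from analyses of all genes, and HAND1, 1 of them and named here after its values were seen, has the fourth widest margin in tumour 4.

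Of the list medians and gene levels tested, 39 (17.9%) had 1 tumour so far from the rest that the gap to its nearest neighbour, divided by the whole range, exceeded Dixon's 95% critical value for 6 samples. Chance flags about 1 in 20 groups, but levels of co-regulated genes are not independent, and some genes were named for a large SD, which favours such gaps, so the share cannot be set against that rate. Tumour 4 was the extreme one in 27 of the 39, the lowest in 23 and the highest in 4.

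Among lists, tumour 4 was lowest for TEAD factors and VGLL cofactors (ratio 0.714), tip cell genes (0.661) and neutrophil genes (0.630), and highest for Hippo kinases and adaptors (0.641). Among single genes it was highest for TEAD2 (0.807), KIT (0.792) and KAT2B (0.674). It was lowest for TEAD4 (0.843), GATA2 (0.797), ECSCR (0.758), KRT18 (0.743), EGFL7 (0.742), MMRN1 (0.698), S100A9 (0.675) and VCAN (0.628). It was also lowest for the lysosomal protease CTSD (0.771), the ribosomal genes RPS3 (0.750) and RPS27 (0.722), TPT1 (0.745), GAPDH (0.727), TMSB10 (0.701), DUSP1 (0.701), VIM (0.700), ANGPTL4 (0.673), WDFY1 (0.660), EEF1A1 (0.658) and TYMS (0.634).

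By FPKM, tumour 1 was highest for the epithelial (0.694) and keratinocyte (0.734) lists, the latter at a median of only 0.474. Of the members with at least 10 counts, 9 of 12 and 4 of 7 were also highest there in CPM. Tumour 2 was lowest for C1QC (0.678), C1QB (0.647) and C1QA (0.628). Tumour 3 was highest for skeletal muscle genes (0.634), at a median of 0.185, and lowest for KAT14 (0.649). Tumour 5 was highest for TBC1D17 (0.737) and IGFBP7 (0.676), and tumour 6 for osteoblast and osteoclast (0.778), adipocyte (0.749) and fibroblast and collagen genes (0.689). The ratio ignores the size of a gap. TBC1D17 stood at 58.5 CPM in tumour 5 and 50.7 to 52.6 CPM elsewhere. WDFY1 stood at 46.9 CPM in tumour 4 and 51.2 to 53.6 CPM elsewhere. Both were among the 10 steadiest genes, so these gaps are small.

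The library labelled EHE 4 stood apart in endothelial genes, TEAD4, KRT18 and KIT. The values argue against depth or scaling, since its pan-endothelial score lay at least 3.77 log2 units below the mean of the others (−3.771 with library size alone) and its total count inside their range. More stroma was taken to mean that the stromal lists rise together, but their median difference of 0.272 fell between the bounds first written. A further bound, added after that, counted 3 of 7 lists, over all members but KIT, above and 3 below the others by more than their SD. The lists thus did not rise together, but stroma of another makeup could also split them, so this test cannot exclude stroma. Over the members past the filter 2 lists were above and 3 below (median 0.492), or 3 and 2 with KIT kept (median 0.619, past the first bound of 0.5). In these log2 CPM scores neutrophil and fibroblast genes were below each time. By FPKM the neutrophil median was also lowest in tumour 4 (0.565). The fibroblast median was not: 4.86 in tumour 4, above tumours 2 (4.52) and 5 (4.44). Tissue of another lineage stays open. The 10 markers of interstitial cells of Cajal were picked for the high KIT and ETV1 but were absent from the fixed lists. ETV1, chosen after its values were seen, stood at 1282 CPM, against 3.804 to 36.0 CPM in the others. The markers had a median difference of 5.618 log2 units, and 9 of 10 were highest in tumour 4, although BARX1 had 0 counts. Such tissue behind the label could give these values. Levels of other lineages in tumour 4 were given only by the fixed lists, and none was tested there with markers of this kind. The labels name no group by which another biological explanation could be tested.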

How the results depend on the processing

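The alternatives CPM per kilobase of exon, leaving out FPKM zeros of genes with at least 10 counts, leaving out genes shared by the hypoxia and tip cell lists, and leaving out each tumour for correlations, similarity and abundant genes were chosen after seeing the data. Of 1089 recomputed values, 989 stayed on the same side and within the spread. Much of this count was fixed beforehand and does not measure robustness. A mean list level can hardly leave the spread when 1 tumour is dropped. A correlation that did not pass at first counts as unchanged while it still fails with the same sign. With 1 tumour left out, 13 moved, 30 no longer passed, 2 newly passed and 2 changed sign; under other settings these numbers were 37, 11, 2 and 3. No paired analysis was possible because the labels give 1 group; the comparisons within tumours pair genes, not samples. With 5 tumours the smallest exact p is 0.0625, so every passing comparison within tumours is lost by construction when 1 is left out. Other causes were not tested; depth limits genes with few counts.

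Lists at or below the 5th percentile in every tumour numbered 3, but 6 with means over members or with CPM, 9 against random lists from filtered genes and 0 with filtered members, where those 3 lists keep too few members for a level. Without 1 tumour they numbered 3 to 6, and lists at or above the 95th percentile 6 to 11, the latter without tumour 4. With means over members, arterial minus venous passed at −0.942 and macrophage minus T and NK cell did not at 1.799; with filtered members the former passed at −1.732. In CPM without length, CAMTA1 minus CAMTA2 was 2.027, TFE3 minus TFEB 2.034, pan-endothelial minus lymphatic 1.482, minus epithelial 5.537 and macrophage minus T and NK cell 2.485, none passing, and TEAD1 minus TEAD4 turned to 1.78. In CPM per kilobase the same 5 were 1.209, 2.248, 1.352, 4.071 and 1.764, none passing. Without 1 tumour they ranged from 0.984 to 1.440, 1.116 to 1.372, 1.551 to 2.340, 4.840 to 5.652 and 1.879 to 2.551.

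Genes beyond counting error numbered 27989 of 38673 (72.4%) with no filter, against 14113 of 14194 (99.4%). By FPKM, r turned to −0.377 for CAMTA1 with YAP/TAZ targets and to −0.762 for WWTR1 with CAMTA1. Without 1 tumour, r ranged from −0.0946 (without tumour 4) to 0.856 for CAMTA1 with YAP/TAZ targets and from −0.910 (without tumour 4) to 0.755 for proliferation with pan-endothelial genes. It ranged from 0.744 to 0.940 for macrophage with T and NK cell genes and from 0.536 to 0.931 for hypoxia with tip cell genes, and both passed without tumour 6, the latter only with the 2 shared genes in both lists (adjusted p 0.2 without them, exact permutation test). The median rho between tumours was 0.4535 over the 500 most variable genes, and 5 of the 15 most abundant genes were shared by CPM.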

Other observations

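The test of a single scaling factor per library was chosen only after the result was seen; the tests of isoforms and of liver genes were written before their values were seen.

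Several of the most variable genes differed widely between tumours. ABCA4, a retinoid transporter, stood at 1614 CPM in tumour 5 and 1078 CPM in tumour 2 but at 2.52 and 1.64 CPM in tumours 1 and 4. SEMA3D, a secreted guidance molecule, stood at 758 and 177 CPM in tumours 2 and 3 and at 0.725 to 21.6 CPM in the others. TSPAN8 reached 307 CPM in tumour 6 and had 0 counts in tumour 4, which allows up to 0.0822 CPM before TMM scaling. The matrix genes COMP (397 CPM) and LRRC15 (164 CPM) were highest in tumour 6, where PRELP (719 CPM) was as well, and all 3 were below 1 CPM in tumour 4. MT-RNR2, a mitochondrial ribosomal RNA chosen after its values were seen, had 475356 counts in tumour 1 and 1293 to 3390 in the others.

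CAMTA1 ranked the tumours differently in counts and in FPKM, with tumours 5 and 3 highest in CPM (488 and 389) and lowest in FPKM (46.3 and 40.4). The values argue against a single factor per library, since after removing each library's median ratio the SD of CAMTA1's log2 ratio was 1.453 (0.154 for WWTR1), at percentile 99.9 of 3607 genes. Apportioning of reads to isoforms stays open: across genes, which are not independent replicates, the SD rose with the number of annotated transcripts (Spearman's rho 0.2241), of which CAMTA1 has 16 and the median gene 9. This is consistent with isoform apportioning in the FPKM estimate, but a rho of this size leaves most of the variation unexplained, and no biological explanation was tested.

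Liver genes were higher in tumours 1 and 2 than in the others, with the list at percentiles 78.4 and 55.9 there. Of 19 hepatocyte genes held out from the fixed lists, 17 (89.47%) had both highest values in those tumours, the exceptions being CPS1 and CYP2C8. That share argues against a few genes transcribed by the tumour cells themselves, for which under 25% was written beforehand, and is consistent with liver tissue in the sampled pieces. ALB stood at only 78.6 and 82.1 CPM there. The labels name no group by which another biological explanation could be tested.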
